A study of Phaseolus vulgaris with 4 samples.

How the data were processed

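Cy5-labelled antisense RNA made from 1 µg of total nodule RNA was hybridized to CombiMatrix 90K custom arrays, per the labels' protocols. The 4 arrays were placed in groups by the strain and treatment in their titles, 1 array per group. Per the file headers, the deposited scanner tables gave for each of 30229 probes the median, mean and SD of spot intensity over the replicate spots, with the number of spots used and left out. Most transcript probes had 3 spots. Each array had 93311 spots, of which 6 were left out on CE3 control, 4 on VHb control, 25 on CE3 paraquat and 39 on VHb paraquat. The scanner, the image software and any spot filter are not given in the sources used here. The intensity columns were linear and reached the ceiling of 65535 for 1, 8, 5 and 4 probes on these arrays, and the authors gave no local background column.

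A deposited table per array held log2 values that were quantile normalized, per the file headers. The log2 scale was inferred from the values. The series table held the same values, with a largest difference of 0. The median was 8.56 on each array. The submitters' processing notes name limma without a version. The shared distribution of these values was not the mean of the 4 arrays, so the arrays that entered the authors' normalization are unknown. The deposited log2 values were used as an alternative.

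The comparisons started from log2 of the median spot intensity per probe as the files gave it, which replaces the mean over spots planned beforehand. No background was subtracted. All 30229 probes were quantile normalized together over the 4 arrays with limma 3.58.1 in R 4.3.3. Then 137 control probes were left out, of which 54 were factory controls and 83 carried names of records from other organisms, including Escherichia coli genome sections and hepatitis C virus. The 83 were chosen by name after the files had been opened. Probes of a record were averaged, which concerned 3 records with 15 probes. The 30% of records with the lowest mean over the arrays were left out. The files held 0 gene names, and 0 record identifiers matched the reference table of gene names.

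Single-pair comparisons are log2 differences between 2 arrays, counted at 1 log2 unit or more, with no test. Their standard errors come from the SD over replicate spots and cover spot noise only. The errors are approximate, since they are for means of unnormalized intensities and the differences are of normalized medians. Overlaps were set beside the number that independent lists would share. The additive limma fit (lmFit and eBayes, two-sided, Benjamini-Hochberg 0.05) used strain and treatment over all 4 arrays. On data simulated for the paraquat effect in the 21056 records, it called 16% of 50 records changed by 1 log2 unit, 94% at 2, 100% at 3 and 100% at 4. It also called 4 unchanged records. The simulation gave every record and array independent noise of the same spread, and no VHb or strain-dependent effect. It therefore does not show how the fit behaves with an array that stands apart. Nothing says that the arrays came from separate cultures. In the main setting the fit gave every record 1 common standard error (0.383), pooled over all records. Its p-values therefore scale a record's size by that common spread and measure no spread between plants for that record.

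A record was called above the control-probe limit on an array where its normalized value exceeded the 95th percentile of the control probes there, a limit chosen after the data had been seen. Where the dimmer array was not above its limit, the fold is given as at least the ratio of the brighter value to that limit. Brightness-matched sets were 10000 random draws within 20 bins of mean log2 value, also added after the data had been seen, as was the set of 33 records whose probes hold GTCTCCC.

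The comparisons, the size of 1 log2 unit, the additive fit, the filter and the rule for named records were fixed before the data were examined. That rule allowed at most 2 identifiers each way per comparison where no descriptions were given. They are those with the largest mean difference among records at or beyond 1 log2 unit the same way in both pairs, and the largest difference between strains. Alternatives chosen beforehand were median centring, cyclic loess, the authors' values, no filter, a 50% filter, the median over probes, a size of 1.5 and a trended robust prior. Added after seeing the data were a normexp background from the control probes (offset 50), the mean over spots in place of the median, and removal of the trend on probe base composition. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the counts.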

Results

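Root nodules of common bean (Phaseolus vulgaris, cultivar Negro Jamapa 81) were profiled on a custom oligonucleotide array. Nodules are the root organs in which rhizobia fix nitrogen. The plants had been inoculated with Rhizobium etli CE3, the wild type, or with CE3 carrying a plasmid with the gene of the Vitreoscilla hemoglobin VHb, a bacterial oxygen-binding globin. Paraquat, a herbicide that generates superoxide, was given at 1 mM for 48 h from 16 days after inoculation, and nodules were harvested at 18 days. The series asked how VHb in the symbiont affects nodule transcripts under this oxidative stress. There was 1 array for each of 4 groups, named here CE3 control, VHb control, CE3 paraquat and VHb paraquat. No group had a replicate, so the number of arrays limits the precision of every comparison.

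Each array held 30092 probes for 30080 sequence records, 35 to 40 nt long, and 137 control probes. The probe names gave a record identifier and a number read here as the position in the record, a meaning that no source used here states. They gave no gene name, so the records are reported by identifier. After the dimmest 30% were left out, 21056 records were compared, of which 9147 (43.4%) had identifiers that begin with TC. The median intensity of the transcript probes was 261 on CE3 control, 291 on VHb control, 219 on CE3 paraquat and 314 on VHb paraquat. The 95th percentile of the control probes was exceeded by 21.9% of the transcript probes on CE3 control, 31.7% on VHb control, 33.6% on CE3 paraquat and 33.7% on VHb paraquat.

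The CE3 control array stood apart from the other arrays. Its replicate spots had a median coefficient of variation of 28.0%, against 14.4% on VHb control, 11.9% on CE3 paraquat and 19.5% on VHb paraquat. Across records its normalized values had Pearson r of 0.834 with VHb control, 0.829 with CE3 paraquat and 0.759 with VHb paraquat, whereas the other 3 arrays had r between 0.929 and 0.939 with each other. Records are not independent replicates. The TC records lay at a median of -0.25 log2 units on CE3 control relative to the mean of the other 3 arrays, and the remaining records at 0.11. TC records were also brighter (median level 9.18 log2 units, against at most 8.70 in other identifier groups of 100 records or more). The CE3 control array entered the paraquat comparison in CE3 nodules, the VHb comparison in control nodules and the difference between strains. With 1 array per group none of these could be computed without it.

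**Figure D1:**
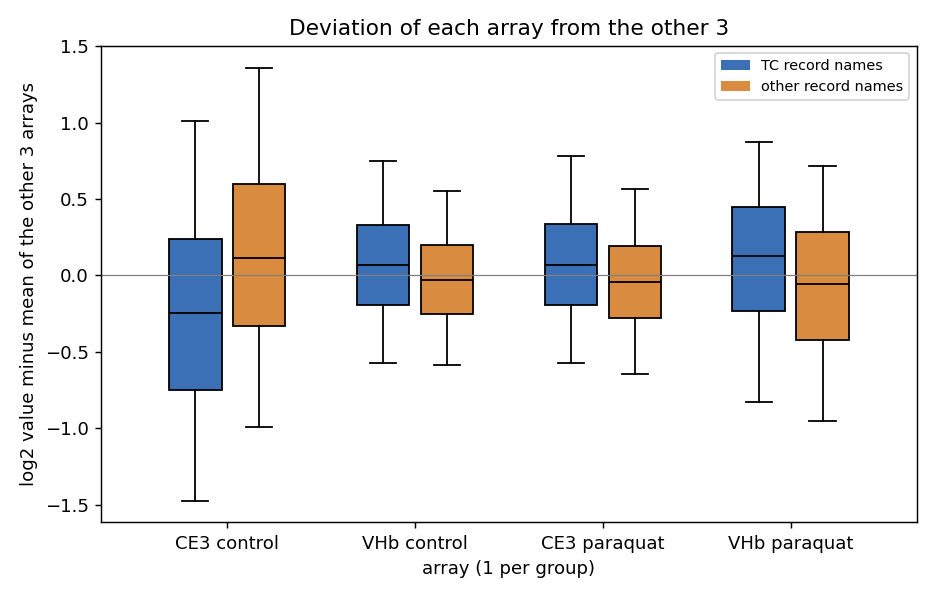
Normalized log2 value of each array minus the mean of the other 3 arrays, for TC records (blue) and other records (orange). Lines in the boxes are medians, boxes span the quartiles and whiskers the 5th to 95th percentiles over records. On CE3 control the medians were -0.25 for TC records and 0.11 for the others.

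The first question was which transcripts differed with paraquat in nodules of either strain. Among the records higher in both strains, TC8774 (35-nt probe at position 796) and TC13823 (37-nt probe at position 436) had the largest mean measured differences, an order that is not established because both were below the control-probe limit on both control arrays. TC8774 was at least 3.46-fold higher with paraquat in CE3 nodules and at least 3.58-fold higher in VHb nodules. TC13823 was likewise at least 8.97-fold higher in CE3 nodules and at least 4.37-fold higher in VHb nodules. Among the records lower in both strains, BE821815 (36-nt probe at position 431) was 6.63-fold lower with paraquat in CE3 nodules and at least 2.35-fold lower in VHb nodules. DB975588 (35-nt probe at position 420) was 10.1-fold lower in CE3 nodules and 3.06-fold lower in VHb nodules. Its probe was 1 of 33 that hold the base sequence GTCTCCC. These 33 records had a median deviation of 2.60 log2 units on CE3 control from the other 3 arrays, and median paraquat differences of -2.05 in CE3 nodules and -0.32 in VHb nodules.

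Where both arrays were above the limit, the log2 differences, with standard errors from the replicate spots of a probe alone, were -2.73 ± 0.44 for BE821815 in CE3 nodules, and -3.33 ± 0.31 and -1.61 ± 0.26 for DB975588 in CE3 and VHb nodules. Spot errors do not include the spread between plants or hybridizations.

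In total, 115 records were higher and 127 lower by at least 1 log2 unit in both strains, where independent lists of the same sizes would share 21.4 and 50.2. The 2 differences shared no array. Another 27 records passed this size in opposite directions, against 74.6 for independent lists. TC records made up 89 of the 115 higher records (77.4%) and 25 of the 127 lower records (19.7%). Random sets of records matched on brightness held 59.6% (95% range 51.3% to 67.8%) and 51.1% (42.5% to 59.1%) TC records. Other processing moved these counts to 82 higher and 54 lower with the authors' normalized values, 102 and 49 with the trend on probe base composition removed, and 70 and 113 with the arrays centred on their medians. They rose to 171 and 150 with the background of each array modelled on its control probes. Across records the paraquat differences of the strains had a Pearson r of 0.309 and a Spearman rho of 0.279. Pearson r was 0.144 after median centring and 0.3645 with the control-probe background. With quantile normalization r was 0.324 within TC records and 0.290 within the others.

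**Figure D2:**
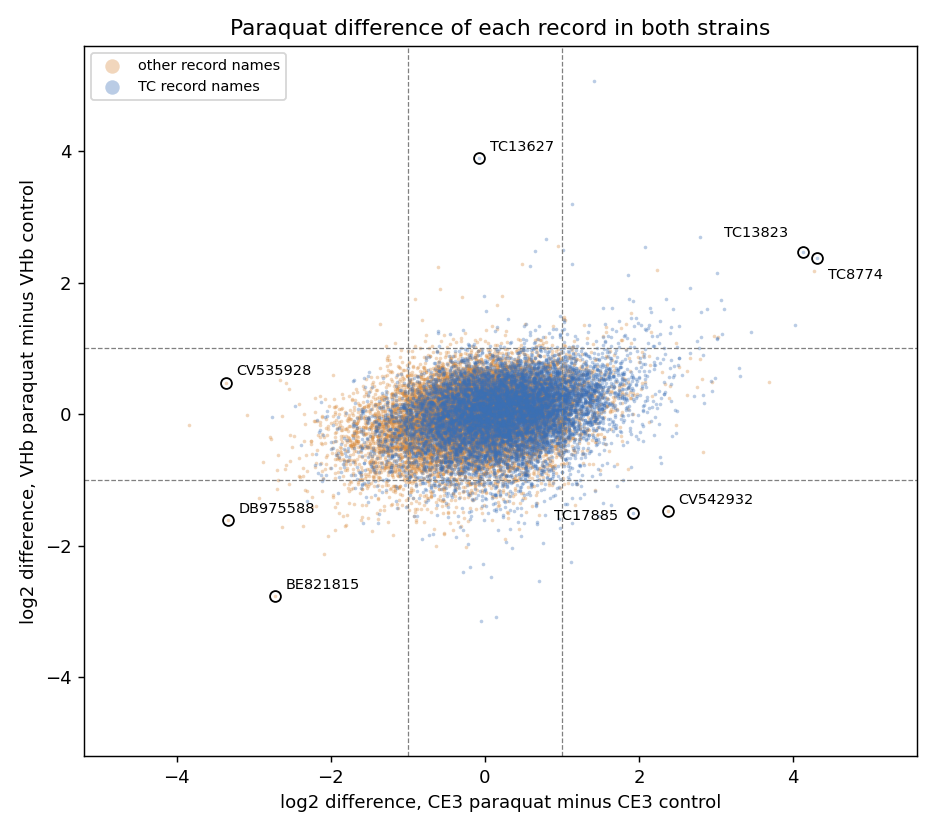
Paraquat minus control log2 difference of each of the 21056 records in CE3 nodules (horizontal) and VHb nodules (vertical), with TC records in blue and others in orange. Dashed lines mark 1 log2 unit, circles the records named for the paraquat comparison and for the difference between strains. The spread was wider in CE3 nodules (SD 0.760) than in VHb nodules (SD 0.484).

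In CE3 nodules 1945 records were higher and 1770 lower with paraquat by at least 1 log2 unit, and in VHb nodules 232 were higher and 597 lower. The SD of the difference over records was 0.760 in CE3 nodules and 0.484 in VHb nodules. TC records made up 70.8% of the higher and 24.3% of the lower records in CE3 nodules, and 62.9% and 44.2% in VHb nodules. These counts are sizes without a test, and the larger counts in CE3 nodules rest on the array that stood apart. When the arrays were centred on their medians in place of quantile normalization, 3747 records were higher and 825 lower in CE3 nodules, and 106 were higher and 1085 lower in VHb nodules.

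A test of paraquat was possible only with the strains as repeats of each other, in an additive limma fit with strain and treatment and 1 residual degree of freedom. TC8774 (limma adjusted p = 5.33e-14) and TC13823 (limma adjusted p = 8.52e-14) rose, and BE821815 fell (limma adjusted p = 2.78e-09). These p-values rest partly on values below the control-probe limit, so no size is given. DB975588, above the limit on every array, fell by 2.47 log2 units (limma adjusted p = 2.58e-07). These records had been chosen for a shared direction and the largest mean difference over both strains, which is the value the fit tests. Their p-values therefore restate that choice and give no support beyond it. The probe of DB975588 holds GTCTCCC, and the 33 records with this sequence had a median deviation of 2.60 log2 units on CE3 control. At an adjusted p of 0.05, 182 records rose and 161 fell, of which 76.9% and 23.0% were TC records. The moderated fit gave every record the same standard error of 0.383, so the call depended on size alone. Any true difference between strains counted as noise in that shared error, and not against the record that showed it. A call therefore does not show that the strains agreed in size. Of the 182 and 161 records, 90 and 79 passed 1 log2 unit in both strains, and 181 and 159 had the same sign in both. With the background of each array modelled on its control probes, no record passed in limma, while 2115 had an unadjusted p under 0.05. In that setting each record's own spread entered its standard error (prior degrees of freedom 2.785, against infinite in the main fit). After median centring 48 rose and 3 fell.

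The second question was which transcripts differed between nodules formed by the VHb strain and by CE3. FE685394 (36-nt probe at position 712) was at least 4.74-fold higher with VHb in control nodules and 3.38-fold higher in paraquat nodules. TC8268 (35-nt probe at position 2003) was at least 1.49-fold higher in control nodules and 31.8-fold higher in paraquat nodules, where its intensity was 34967.5 on VHb paraquat and 993.5 on CE3 paraquat. In control nodules only its measured difference (1.34 ± 0.29 log2 units, spot error) reached 1 log2 unit, and the bound of 0.58 did not. FE697850 (38-nt probe at position 351) was 8.54-fold lower with VHb in control nodules and at least 3.43-fold lower in paraquat nodules. GR830646 (39-nt probe at position 573) was 14.0-fold lower in control nodules and 3.98-fold lower in paraquat nodules. The probes of FE697850 and GR830646 both hold GTCTCCC, and the 33 records with this sequence had median VHb differences of -2.44 in control nodules and -0.68 in paraquat nodules.

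Where both arrays were above the limit, the log2 differences, with spot errors, were 1.76 ± 0.14 for FE685394 and 4.99 ± 0.23 for TC8268 in paraquat nodules and -3.09 ± 0.74 for FE697850 in control nodules. They were -3.80 ± 0.35 in control and -1.99 ± 0.37 in paraquat nodules for GR830646. With VHb, 85 records were higher and 155 lower by at least 1 log2 unit in both conditions, against 24.8 and 54.1 for independent lists, and 28 passed in opposite directions, against 83.1. Median centring gave 20 higher and 124 lower, and a background modelled on the control probes gave 155 and 183. TC records made up 77.6% of the 85 higher and 31.6% of the 155 lower records, where brightness-matched sets held 58.2% and 58.1%. Across records r was 0.289 between the conditions, 0.0909 after median centring and 0.3584 with the control-probe background.

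In control nodules 1948 records were higher and 1723 lower with VHb, and in paraquat nodules 268 were higher and 661 lower. The SDs over records were 0.747 and 0.488. TC records made up 70.0% of the higher and 25.7% of the lower records in control nodules, where the CE3 control array was the reference, and 51.1% and 48.0% in paraquat nodules. Median centring gave 3180 higher and 692 lower in control nodules, and 128 higher and 1477 lower in paraquat nodules.

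In the additive limma fit FE685394 (limma adjusted p = 4.76e-14) and TC8268 (limma adjusted p = 1.52e-12) rose with VHb, and FE697850 fell (limma adjusted p = 3.34e-12), each with 1 array below the control-probe limit. GR830646, above the limit on every array, fell by 2.90 log2 units (limma adjusted p = 2.17e-10). These records had been chosen for the largest mean VHb difference over both conditions, which is the value tested, so their p-values restate that choice. The probes of FE697850 and GR830646 hold GTCTCCC. The 33 records with this sequence had a median deviation of 2.60 log2 units on CE3 control. In this fit 115 records rose and 109 fell with VHb, and TC records made up 83.5% and 30.3% of them. There were 49 records called for both paraquat and VHb, and 46 of them had the same sign for both. Both effects were measured on the same 4 arrays, CE3 control included, and share their errors, so this overlap is given without a value for chance. With control-probe background modelling no record passed for VHb in limma (2155 at an unadjusted p under 0.05), and median centring left 18 that rose and 8 that fell.

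**Figure D3:**
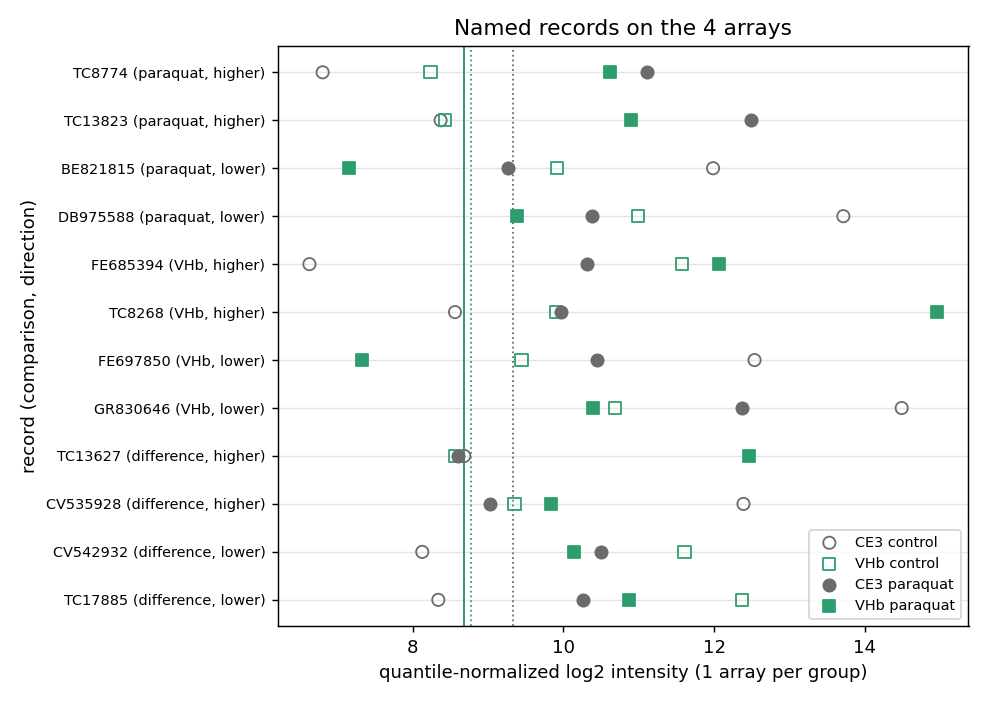
Quantile-normalized log2 intensity of the 12 named records on each of the 4 arrays, 1 point per array. Circles are CE3 and squares VHb, open symbols control and filled symbols paraquat. Vertical lines mark the 95th percentile of the control probes, dotted for the control arrays (9.33 for CE3, 8.77 for VHb) and solid for the paraquat arrays (8.68 and 8.67), and TC8774 lay below these lines on both control arrays.

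The third question was whether the paraquat difference depended on the strain. No test was possible, because this contrast used the last degree of freedom. TC13627 (38-nt probe at position 1101) was at least 12.9-fold higher with paraquat in VHb nodules and was below the control-probe limit on both CE3 arrays. CV535928 (35-nt probe at position 599) was 10.3-fold lower with paraquat in CE3 nodules and 1.40-fold higher in VHb nodules. Its probe holds GTCTCCC, and its log2 value was 12.39 on CE3 control against 9.35 on VHb control, 9.03 on CE3 paraquat and 9.83 on VHb paraquat. CV542932 (38-nt probe at position 118) was at least 2.25-fold higher with paraquat in CE3 nodules and 2.78-fold lower in VHb nodules, and TC17885 (36-nt probe at position 329) at least 1.91-fold higher and 2.83-fold lower.

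The paraquat difference was higher in VHb than in CE3 nodules by at least 1 log2 unit for 1695 records and lower for 2236, and 26.1% and 63.9% of these were TC records. As contrasts of 2 arrays against 2, the SD over records was 0.510 for paraquat, 0.502 for VHb and 0.382 for the strain-by-treatment contrast. At a mean difference of 1.28, the smallest size called for paraquat in the additive fit, 343 records passed for paraquat, 274 for VHb and 45 for the strain-by-treatment contrast. The CE3 control array entered all 3 contrasts. After median centring 772 records were higher and 5646 lower in the difference between strains.

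The 39 gene lists fixed before the data were examined, among them antioxidant enzymes, nodule proteins and cell type markers, had 0 members, since they were defined on gene descriptions. No list could therefore be described.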

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

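All tests of explanations in this part were chosen after the results were seen. The strain-dependence of the paraquat difference was not tested for any record, since no residual degree of freedom was left. All 4 records named for the difference between strains had paraquat differences of opposite measured sign, but that of TC13627 cannot be read in CE3. VHb minus CE3 was 3.85 for CV535928 (-3.37 ± 0.37 in CE3, 0.48 ± 0.35 in VHb, spot errors). The measured values were -3.84 for CV542932 and -3.42 for TC17885, but neither was above the control-probe limit on CE3 control. Their CE3 differences are therefore only at least 1.17 and 0.93, against -1.47 and -1.50 in VHb, and the strain differences are not exact. TC13627 had an intensity of 6384.5 on VHb paraquat and was not above the control-probe limit on the other arrays, both CE3 arrays included. At 1 log2 unit or more, 27 records went in opposite directions with paraquat in the strains, and 28 with VHb in the conditions. A control probe named for a section of the Escherichia coli genome (AE000185) had an intensity of 2387 on CE3 control, 2168 on VHb control, 1239 on CE3 paraquat and 954 on VHb paraquat, above the 95th percentile of the control probes.

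The deviation of CE3 control from the other 3 arrays bears on most of these results. Noise between replicate spots was estimated at 13.25% of the variance of this deviation. The estimate is approximate, since it is for means of unnormalized intensities and the deviation is of normalized medians. Removing the trend on single-base and dinucleotide content left the SD of the deviation at 0.7183, from 0.760. These values argue against either as the whole cause. For 33 records whose probes hold the word GTCTCCC, hybridization to a short sequence shared by unrelated probes is a candidate explanation: their median deviation on CE3 control was 2.6045 log2 units, and 32 of 33 were above the mean of the other 3 arrays. The word was noticed in DB975588, FE697850, GR830646 and CV535928 and ranked first of 8867 words of 7 bases, in a search over 15609 words of 5 to 8 bases and 8 contrasts; without these 4 records the median was 2.55. What set the rest of the array apart stays open, including the plants themselves, which cannot be separated from the array with 1 array per group.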

How the results depend on the processing

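Of 108 comparison values recomputed, 76 stayed within 1.5 times. So did the 108 values of the named records, with 0 reversed. Of these, 36 could not move, since 3 settings (both filters and the median over probes) leave a single-probe record unchanged. The named values are log2 differences, averaged over both pairs except for the difference between strains. The limit of 1.5 applies to log2 values, so folds can change more, and folds of single pairs were not checked. After median centring the strain difference of CV535928 went from 3.85 to 2.80 log2 units. The cause of the larger changes in comparison values was not tested, except that a size of 1.5 counts fewer records by construction. No paired analysis was possible because each group had 1 array. The background alternative planned was the setting used, and gene lists had no members, so neither was run. Median centring shifted the median difference to 0.24 (paraquat, CE3), -0.14 (paraquat, VHb), 0.19 (VHb, control) and -0.18 (VHb, paraquat). It gave 1605 records for VHb in paraquat nodules, 144 for VHb in both conditions (20 higher, 124 lower), 6418 for the difference between strains, r of 0.144 for paraquat and 0.0909 for VHb, and 51 and 26 additive calls for paraquat and VHb. The authors' values gave 2268 (paraquat, CE3), 367 (paraquat, VHb), 136 (paraquat, both; 82 higher, 54 lower), 2247 (VHb, control), 364 (VHb, paraquat), 126 (VHb, both), 2081 (difference) and 591 and 567 additive calls. In the same order, a size of 1.5 gave 1066, 127, 37, 936, 136, 30 and 996. Spot means, chosen after seeing the data like the next 2 alternatives, gave 599 for VHb in paraquat nodules, 155 for VHb in both conditions and 565 additive calls for paraquat. Removing the composition trend gave 151 for paraquat in both strains (102 higher, 49 lower), 155 for VHb in both conditions and 208 additive calls for paraquat (147 rose, 61 fell). Control-probe normexp gave 0 additive calls for paraquat and 0 for VHb in limma, with 2115 and 2155 at an unadjusted p under 0.05. A trended robust prior gave 227 for paraquat. Cyclic loess turned the split of additive calls to 172 up and 188 down for paraquat and 80 and 132 for VHb, and that of sizes to 1523 and 1611 (paraquat, CE3) and 1416 and 1486 (VHb, control). Spot means turned additive paraquat to 273 and 292. Leaving out the filter turned paraquat in CE3 nodules to 2060 and 2117 and additive paraquat to 229 and 230. Control-probe normexp turned paraquat in CE3 nodules to 1753 and 1765 and paraquat in both strains to 171 and 150. The trended robust prior turned additive VHb to 71 and 80, and a size of 1.5 turned paraquat in both strains to 22 and 15. CE3 control had the lowest correlations under every setting. Signal over background limits the dim records: 31.3% of compared records were above the control-probe limit on CE3 control and 45.2% to 48.1% on the others.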

Other observations

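All tests of explanations in this part were chosen after the results were seen. On CE3 control 37 records lay at least 2 log2 units above all other arrays and 37 at least as far below. The counts were 3 and 0 on VHb control, 0 and 0 on CE3 paraquat and 8 and 3 on VHb paraquat. Of the 8 records far above on VHb paraquat, 7 were TC records, with a median spot error of 0.12 for the difference from CE3 paraquat. TC8268 and TC13627 were among them. Grouped by the letters that open their identifiers, 27 groups had 100 records or more. The median paraquat difference in CE3 nodules was above 0 in 6 and below 0 in 21, ranging from -0.41 to 0.24. The 6 groups above 0 were the brightest, with median levels from 8.41 (EX) to 9.18 (TC) log2 units. The 21 groups below 0 reached at most 8.33 (FG), so identifier and brightness were not separated. In VHb nodules it ranged from -0.20 to 0.10.

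The 127 records lower with paraquat in both strains were mostly not TC records, and at this size their number ranged with the processing from 49 after removal of the trend on probe base composition and 54 with the authors' values to 150 with control-probe normexp. A general fall of signal on probes without a plant target would lower the control probes too, but among the 49 control probes that passed the brightness filter the median paraquat difference was -0.20 in CE3 nodules and 0.0251 in VHb nodules, and among the brightest 20 it was -0.63 and -0.08, with 9 lower in both strains and 15 above the mean of the other 3 arrays on CE3 control. None (0 of 49) was lower by 1 log2 unit or more in both strains, the size that defines the 127, but the probes went both ways and are few, so the explanation stays open. The word GTCTCCC was held by 5 of the 127, against 0.20 by its share of all records. It was held by 11 of the 155 records lower with VHb in both conditions, against 0.24. The word was noticed in named records, among them DB975588 and FE697850, which belong to both sets. It was then ranked by signal on CE3 control, an array that enters both sets. An excess was therefore built into the choice of the word and is no independent support. Since 122 of the 127 did not hold GTCTCCC, this word alone does not account for the set of 127. Records with other words were also high on CE3 control, such as CCTCCCC (39 records, median deviation 1.11) and CTCCCCT (62 records, 0.89). Records with GTCTCCC were not left out of these groups, so the groups may overlap with it. CCTCCCC and CTCCCCT were not checked in the 127, so hybridization to other short sequences stays open. An effect of paraquat also stays open and was not tested apart from the arrays.

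The paraquat differences of the strains went together across records. With the trend on probe base composition removed, r was 0.2266, from 0.309, so that trend accounts for a part at most, while median centring lowered r to 0.144. A single gradient of signal from CE3 control through VHb control and CE3 paraquat to VHb paraquat was tried as another explanation. Its order was that of some bright control probes, such as AE000185, but not of all. The brightest by the mean of the other 3 arrays had log2 values of 10.35 on VHb control and 10.56 on CE3 paraquat. Of the 242 records at or beyond 1 log2 unit in both strains 64.05% followed this order or its mirror (79.5% of the lower and 47.0% of the higher records). It would be 16.7% if the 6 possible orders were equal. Shuffling each array's deviations from the record means over records gave 77.7% (66.0% to 90.7% in 100 shuffles), above the observed share each time. CE3 control (SD 0.760) and VHb paraquat (SD 0.532) had the widest deviations from the other arrays and stand at the ends of the order. The shuffles kept the selection by size and these spreads, which alone gave a high share. The observed share therefore cannot decide for or against a gradient. A gradient and a response to paraquat common to both strains cannot be told apart here.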
